A study of Homo sapiens with 24 samples.

How the data were processed

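The series holds 24 single-colour Agilent gene expression arrays of Jurkat cells treated with 5 nM FK866 or DMSO (mock) for 48 h, read for polysomal, subpolysomal and total RNA, 4 biological replicates in each of 6 groups. Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 10.7.3.1, whereas the submitters' processing notes name version 10.7.7.1; the headers name the human build hg19 for probe positions. The deposited spot intensity used here is Feature Extraction's processed signal, which per the file headers is background-subtracted and detrended within an array, with no normalization between arrays. The mean and local background intensity of each spot, also per the file headers, served an alternative. The deposited flags well above background, saturated and non-uniform (other values, 0 or 1 per the file headers) were read with them. The authors' table of values holds log2 values, deposited without a stated normalization. Each of its 24 columns matched its own array best among all arrays and had the median 4.73, with 25% and 75% quantiles of 1.73 and 9.0; equal quantiles in each column are what quantile normalization gives. The zero point of that table stays unknown.

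Control spots were left out. Of 34127 probes, 28426 were given a symbol from the reference table of genes: 25771 through the systematic accession, 156 through another accession in the file, 2095 through the symbol and 404 through an older symbol. The file's own name was kept for 5701, and 20469 distinct reference symbols were present. No probe was saturated, and 0 columns of values were left unmapped. The log2 processed signal minus the array's 75th percentile was analysed in R 4.3.3. Probes were kept if well above background on all 4 arrays of at least 1 group (19324 probes), and each gene was represented by its probe with the highest mean signal (15032 genes, 3498 of them with several kept probes). The text says where another kept probe of a named gene had the opposite sign or lay over 1 log2 away.

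Group means of the 6 groups were fitted together with limma 3.58.1 (lmFit, contrasts.fit, eBayes), with 18 residual and 3.49 prior degrees of freedom, in 8 comparisons: FK866 against mock in each of the 3 RNA pools, the 3 differences between these effects, and polysomal against subpolysomal RNA in mock and in FK866 cells. Tests were two-sided, with Benjamini-Hochberg adjustment over genes within a comparison and a threshold of 0.05 on the adjusted p. Unless another tool is named, an adjusted p of a gene is limma's. Tables were read with the data.table package, version 1.17.8, and Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the files and drew the figures. The groups, comparisons, gene lists, rule for named genes and the alternatives not named below as later were fixed before the data were examined. The rule took, per comparison, the 6 largest rises and 6 largest falls among called genes with a reference symbol, no overlap between the groups' replicates and all arrays above background, the 4 largest called members of each described list, and 21 fixed genes (NAMPT, NAPRT, ATF4, DDIT3, ASNS, TRIB3, CHAC1, SESN2, DDIT4, TXNIP, MYC, MCL1, ODC1, CDKN1A, EEF1A1, EEF2, RPS6, TPT1, PABPC1, ACTB and GAPDH), of which CDKN1A was not among the genes kept.

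The 39 gene lists were tested with camera at its preset correlation of 0.01, adjusted over 39 lists and 8 comparisons (312 tests); camera compares a list with all other genes. Lists covered cytosolic and mitochondrial ribosomal proteins, other TOP mRNAs, tRNA synthetases, translation initiation factors, ribosome biogenesis, the proteasome, heat shock, the unfolded protein response, ATF4 targets, mRNAs with upstream reading frames, oxidative phosphorylation, the citric acid cycle, mitochondrial RNAs, NAD metabolism, glycolysis, energy stress, hypoxia, p53, NRF2, apoptosis, autophagy, cholesterol and fatty acid synthesis, MYC targets, proliferation, DNA replication, histones, the spliceosome, KRAB zinc finger genes, T-cell identity and activation, interferon, snoRNA hosts and nuclear RNAs, with markers of B cells, myeloid, erythroid and epithelial or fibroblast cells. Of 87 list calls (57 up, 30 down), 8 held when the correlation was estimated: heat shock in total and polysomal RNA, tRNA synthetases in polysomal RNA, the proteasome and MYC targets in subpolysomal RNA, the proteasome in subpolysomal over total RNA, and other TOP mRNAs in polysomal over subpolysomal RNA of both treatments. With fry, which tests whether a list's genes move on balance one way and does not compare the list with other genes, 35 were called. With scan day as a block and an estimated correlation, camera called 0 of 312 (27 at an unadjusted p under 0.05, lowest adjusted p 0.193). At the preset correlation the block gave 93 calls against 87 without it, and 3 lists lost theirs: cytosolic tRNA synthetases in subpolysomal RNA (adjusted p 0.052), MYC targets for polysomal over total RNA (0.0672) and translation initiation factors for polysomal over subpolysomal RNA (0.0563).

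The headers give 9 slides and 3 scan days, and each scan day held every group. Values are therefore given with scan day as a block (16 residual degrees of freedom) and within each day; later days held 1 array of each group, so they give a fold change and no error. Whether replicate numbers pair the arrays was checked through the correlation, across genes, of same-numbered arrays' deviations from their group means. It was 0.61, 0.78, 0.67 and 0.37 for FK866 and mock total RNA and 0.72, 0.77, 0.77 and 0.72 for subpolysomal RNA, above the bound of 0.1 set for pairing. The pools of 1 treatment passed as well. For polysomal RNA it was 0.77, 0.76, 0.78 and 0.0032, so replicate 4 lay below the bound. Arrays of unlike numbers reached 0.72 in total, 0.82 in polysomal and 0.80 in subpolysomal RNA, so the bound cannot show pairing. Within a treatment, subpolysomal and total RNA matched best by number in 4 of 4 arrays, in mock and in FK866 cells alike. Pairs of pools with polysomal RNA did so in 2 of 4. The labels call the numbers biological replicates and do not say whether pools of 1 number share a culture. Scan day follows the number. The fit without a block takes all arrays as independent, whereas the culture block takes same-numbered pools of a treatment as 1 culture. Alternatives were quantile normalization, median and spike-in centring, the authors' table, normexp background correction with an offset of 50, the filter on dim probes, the mean over probes, the groups in the fit, eBayes with trend and robust, a minimum of 2-fold, blocks for replicate number, culture, slide and scan day, and each array left out. The scan day settings and those leaving out the dim arrays were chosen after the data were seen.

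The fits were tested on simulated data in which 100 of 15032 genes changed by 4-fold and 100 by 2-fold, with scan-day shifts as in these arrays. The fit without a block recovered 46% and 4% of them for FK866 against mock in total RNA, and the fit with scan day as a block 93% and 56%. For polysomal RNA these were 53% and 5% without, 97% and 46% with the block, and for subpolysomal RNA 44% and 1% without, 98% and 39% with it. For the effect on polysomal over subpolysomal RNA, 17% and 0% were recovered without and 82% and 24% with the block. False calls with the block were 4 in total, 8 in polysomal and 4 in subpolysomal RNA, and 4 for that effect. The simulated errors were independent between genes and between arrays. In the real polysomal arrays, another split within scan days gave 620 calls with the block. The simulation therefore does not show how the block performs on these arrays. Transcript structures were not among the reference files, so whether a probe lies in an exon, an intron or a UTR was not analysed.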

Results

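Messenger RNA was measured in Jurkat cells, a human line of T-cell acute lymphoblastic leukaemia, after 48 h with 5 nM FK866 or with its vehicle alone (mock). FK866 inhibits NAMPT, the enzyme of the first step from nicotinamide to NAD. Lysates were spread over sucrose gradients after cycloheximide, which holds ribosomes on mRNA. RNA was taken as polysomal RNA (fractions 8 to 11, mRNA carrying several ribosomes), subpolysomal RNA (fractions 2 to 7) and total RNA (fractions 2 to 11). Each of the 6 groups had 4 biological replicates, each on its own array, 24 arrays in all. Between 43.1% (FK866 polysomal replicate 3) and 67.8% of probes were well above background on an array, and the number of arrays limits the precision. The lowest 75th percentile of signal was 114 units (FK866 subpolysomal replicate 3) and the highest 990 units. Levels are log2 signal over the array's 75th percentile, as mean ± SD (n = 4), and probe positions are on the human build hg19. The arrays were scanned on 3 days, with 2 arrays of each group on day 1 and 1 on each later day. The first principal component held 51.2% of the variance, and scan day accounted for 83.8% of it. The second held 18.3% and followed the fraction (86.1%), and the component after it held 9.5% and followed the treatment (78.5%). Since each day held every group equally, scan day as a block left fold changes and list medians as they were and changed only their error. The median log2 change of all 15032 genes with FK866 was 0.02 in total, -0.13 in polysomal and 0.01 in subpolysomal RNA, and centring on spike-in probes instead moved it to 0.10, 0.78 and -0.79. The spike-in offset had an SD of 1.01 to 1.73 log2 within a group, and the labels do not say whether equal cRNA was hybridised from each pool. The median of the ratio of polysomal to subpolysomal RNA was -0.03 in mock and -0.14 in FK866 cells (0.0033 and 1.60 with spike-in centring, 0.39 and 0.27 with median centring, -0.14 and -0.28 with normexp). Spike-in centring also moved the median difference between FK866 effects from -0.09 to 1.61 for polysomal over subpolysomal, from -0.11 to 0.72 for polysomal over total and from -0.02 to -0.90 for subpolysomal over total RNA. Normexp moved the subpolysomal median to 0.13, and median centring the subpolysomal over total one to 0.12 and the polysomal over total one to 0.02.

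In total RNA, the comparison of FK866 with mock cells asks which mRNAs changed in level. RGS1, a regulator of G protein signalling, rose 5.45-fold, from -3.72 ± 0.57 to -1.27 ± 0.53 (n = 4; log2 change 2.45 ± 0.38 SE, limma adjusted p = 0.0066; chromosome 1, 192548857 to 192548916). LATS1, a kinase of the Hippo pathway, rose 4.29-fold, from -3.41 ± 0.41 to -1.30 ± 0.20 (n = 4; adjusted p from limma 0.000214; chromosome 6, 150022916 to 150022975). JPH2, a junction protein of the endoplasmic reticulum, fell 3.83-fold, from -1.70 ± 0.37 to -3.63 ± 0.51 (n = 4; limma adjusted p = 0.0094; chromosome 20, 42740545 to 42740604). The log2 changes on scan days 1, 2 and 3 were 2.45, 2.28 and 2.60 for RGS1, 2.29, 1.69 and 2.14 for LATS1, and -2.38, -1.86 and -1.14 for JPH2. With scan day as a block their adjusted p were 5.36e-07, 1.84e-07 and 0.000452. A probe of RBM33, an RNA-binding protein, rose 3.99-fold (adjusted p = 0.000214), while the probe of RBM33 with the lowest value gave a log2 change of -0.55. CDC14A, a phosphatase (log2 2.24), and MINPP1 (log2 2.07, its other probe 0.25) rose as well, and PPFIA4 (log2 -1.71), FBLN5 (log2 -1.55) and CLIP3 (log2 -1.50) fell. RGS1, LATS1, CDC14A, PPFIA4, FBLN5 and CLIP3 each had 1 kept probe, so no other probe could check their changes in any pool.

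Among the fixed gene lists, heat shock proteins, chaperones that help other proteins fold, were higher in total RNA of FK866 cells than genes outside the list. Their median log2 change was 0.48 (camera adjusted p = 2.56e-06, and adjusted p = 0.0307 with an estimated correlation), with 0.72, 0.77 and 0.50 on the 3 scan days. Of 19 measured members 1 rose, HSP90AB1 (2.54-fold, log2 1.35 ± 0.29 SE, limma adjusted p = 0.0413), 4 rose when adjusted over the list alone, and 7 with scan day as a block. MYC targets had a median of 0.41 (0.45, 0.86 and 0.08 by day, camera adjusted p = 2.79e-07, and adjusted p = 0.0736 with an estimated correlation), and 1 of 27 rose, 6 adjusted over the list alone and 9 with the block. Ribosome biogenesis genes had a median of 0.49 (0.71, 0.44 and 0.07 by day, camera adjusted p = 1.15e-07, and adjusted p = 0.269 with an estimated correlation). None of the 40 passed alone by limma (0 adjusted over the list alone, 6 with the block). Cytosolic tRNA synthetases, which charge tRNAs, had a median of 0.43 (0.63, 0.02 and 0.22 by day, camera adjusted p = 0.00055, and adjusted p = 0.0796 with an estimated correlation). Of these 20, 0 rose by limma, 1 adjusted over the list alone and 4 with the block. Mitochondrial ribosomal proteins had a median of 0.33, which was 0.24, 0.87 and -0.15 by day, so the direction did not hold on day 3 (camera adjusted p = 4.92e-07, and adjusted p = 0.602 with an estimated correlation). MRPL44 (log2 1.09) and MRPS35 (log2 0.94) were the 2 of 75 members that rose, 3 did when adjusted over the list alone, and 10 with the block. NF-kB and T-cell activation genes had a median of -0.61 (-0.61, -0.62 and -0.81 by day, camera adjusted p = 0.0013, and adjusted p = 0.546 with an estimated correlation), and hypoxia genes -0.44 (-0.60, -0.26 and -0.36; camera adjusted p = 0.0068, and adjusted p = 0.733 with an estimated correlation). No member of either list, of 22 and 20, fell by limma, over all genes or adjusted over the list alone, and 6 and 5 fell with the block. No list median named for total RNA changed sign under another scaling. MTHFD2, a mitochondrial folate enzyme and ATF4 target, rose 2.12-fold, from 3.86 ± 0.34 to 4.95 ± 0.09 (n = 4; limma adjusted p = 0.0296; adjusted p = 0.000823 with the block). ASNS, asparagine synthetase, had a log2 change of 0.86 (adjusted p = 0.0912), DDIT4 -1.30 (0.402), CHAC1 -0.90 (0.738), MYC 1.095 (0.708) and NAMPT itself 0.48 (1, and 0.24 with the block). With scan day as a block ASNS (adjusted p = 0.0039), DDIT4 (0.0019), CHAC1 (0.013) and MYC (0.008) passed.

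By limma, 59 of 15032 genes changed in total RNA, 45 higher and 14 lower, and 56 of them by at least 2-fold. With scan day as a block 1269 passed (584 higher, 685 lower), including all 59. Each of the 59 had the same sign on all 3 days. Called genes were chosen on these same arrays, so neither the block nor the days give independent support, here or in the other pools. The replicate block gave 1078, scan day 1 alone 2488, median centring 32 (8 higher, 24 lower) and spike-in centring 0 (66 at an unadjusted p under 0.05). Of 27 called genes with several probes, 14 had a probe of opposite sign. The count fell to 13 without FK866 replicate 3, 15 without mock replicate 1, 17 without FK866 replicate 1, 19 without mock replicate 2, 24 without mock replicate 3, 25 without FK866 replicate 2 and 38 without mock replicate 4. CDC14A lost its call without FK866 replicate 3 (adjusted p = 0.0534), CLIP3 without FK866 replicate 1 or 3 or mock replicate 2 (up to 0.0715). MTHFD2 lost its call without FK866 replicate 1, 2 or 3 or mock replicate 1 or 3 (up to 0.139), and HSP90AB1 and MINPP1 did in 6 of 8 removals (up to 0.19 and 0.0923). HSP90AB1 kept its call only without FK866 replicate 4 or mock replicate 3, and MINPP1 only without replicate 4 of either group. PPFIA4, FBLN5 and MRPL44 kept theirs only without FK866 replicate 4 (otherwise up to 0.137, 0.2 and 0.128), and MRPS35 in no removal (up to 0.138).

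In polysomal RNA, the same comparison asks which mRNAs changed among those carrying several ribosomes. RGS1 rose 5.54-fold, from -4.00 ± 0.58 to -1.53 ± 0.49 (n = 4; log2 change 2.47 ± 0.38 SE, limma adjusted p = 0.0065). KLHL11, a kelch family protein, rose 4.40-fold, from -2.47 ± 0.42 to -0.34 ± 0.34 (n = 4; limma adjusted p = 0.0014; chromosome 17, 40009940 to 40009999). LATS1 rose 3.93-fold, from -4.22 ± 0.28 to -2.25 ± 0.19 (n = 4; limma adjusted p = 0.0012). By scan day the log2 changes were 2.40, 1.84 and 3.23 for RGS1, 2.49, 1.41 and 2.17 for KLHL11, and 2.17, 1.74 and 1.80 for LATS1, and with scan day as a block the adjusted p were 6.74e-07, 8.25e-06 and 6.21e-07. Probes of PHF12 (log2 2.16), RNF213 (log2 2.00) and TMPO (log2 1.97) rose, whereas the lowest other probes of these genes gave -0.28, -0.46 and 0.26. JPH2 (log2 -1.84), CLIP3 (log2 -1.64), PPFIA4 (log2 -1.63), PTPRS, a receptor phosphatase (log2 -1.31), and ADAMTS13, a protease (log2 -1.05), fell.

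Heat shock proteins had a median log2 change of 0.76 in polysomal RNA (0.92, 0.87 and 0.55 by day, camera adjusted p = 6.26e-08, and adjusted p = 0.0307 with an estimated correlation). HSP90AB1 was the 1 of 19 members that rose (2.80-fold, log2 1.49 ± 0.29 SE, limma adjusted p = 0.0246), 2 rose adjusted over the list alone and 6 with the block. Cytosolic tRNA synthetases had a median of 0.47 (0.60, 0.53 and 0.35 by day, camera adjusted p = 9.53e-06, and adjusted p = 0.0307 with an estimated correlation). Of 20, 0 were called by limma, 0 adjusted over the list alone and 1 with the block. Ribosome biogenesis genes had a median of 0.37 (0.67, 0.31 and 0.03 by day, camera adjusted p = 9.82e-09, and adjusted p = 0.203 with an estimated correlation). Of 40, 0 were called, 0 adjusted over the list alone and 6 with the block. Hypoxia genes had a median of -0.45 (-0.59, -0.53 and 0.05 by day, camera adjusted p = 0.01, and adjusted p = 0.754 with an estimated correlation), which turned to 0.46 with spike-in centring. For hypoxia, 0 of 20 were called, 0 adjusted over the list alone, and 6 fell with the block. Replication-dependent histones had a median of -0.57 (-0.17, -0.36 and -1.47 by day, camera adjusted p = 0.0213, and adjusted p = 0.944 with an estimated correlation), which turned to 0.34 with spike-in centring, and 0 of 35 were called in any of the 3 counts. Of the stress genes, DDIT3 had a log2 change of 1.08 (adjusted p = 0.394, 0.0099 with the block), ASNS 0.64 (0.363, 0.0276), TXNIP 0.65 (0.642, 0.0203), MYC 1.08 (0.828, 0.0086), DDIT4 -1.21 (0.542, 0.0033) and CHAC1 -0.86 (0.872, 0.016; 0.04 with spike-in centring).

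By limma, 36 genes changed in polysomal RNA, 24 higher and 12 lower, 35 of them by at least 2-fold. Scan day as a block gave 1276 (462 higher, 814 lower), including all 36, each with the same sign on all 3 days. Day 1 alone gave 1957, median centring 3 and spike-in centring 0 (339 at an unadjusted p under 0.05). Of 15 called genes with several probes, 4 had a probe of opposite sign. The polysomal count was 5 without FK866 replicate 2 or mock replicate 1, 8 without mock replicate 2, 12 without mock replicate 3 and 14 without FK866 replicate 1. CLIP3 lost its call without FK866 replicate 2 or mock replicate 1 (adjusted p up to 0.0526), PHF12 and PTPRS without FK866 replicate 2 or mock replicate 1, 2 or 3 (up to 0.0656 and 0.0723), and JPH2 without FK866 replicate 1 or 2 or mock replicate 1 or 3 (up to 0.0982). RNF213 lost its call without FK866 replicate 1, 2 or 3 or mock replicate 1 or 2 (up to 0.101). HSP90AB1 kept its call only without replicate 4 of either group, ADAMTS13 only without FK866 replicate 3 or 4, TMPO only without FK866 replicate 3, and PPFIA4 only without FK866 replicate 4 (otherwise up to 0.123, 0.134, 0.151 and 0.213).

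In subpolysomal RNA, which holds mRNA with few or no ribosomes, several fixed lists were higher in FK866 cells relative to the array's 75th percentile, by camera at its preset correlation. Oxidative phosphorylation genes, which encode the respiratory chain, had a median log2 change of 0.83 (0.64, 1.57 and 0.32 by day, camera adjusted p = 2.94e-15, and adjusted p = 0.552 with an estimated correlation). Of 74 measured, 15 rose and 0 fell (18 rose adjusted over the list alone, 52 with the block). Their median was 0.03 with spike-in centring. SDHD, a subunit of complex II, rose 3.07-fold, from 1.57 ± 0.37 to 3.19 ± 0.15 (n = 4; log2 change 1.62 ± 0.25 SE, limma adjusted p = 0.00066), and ATP5MC3, a subunit of ATP synthase, rose 2.85-fold. Mitochondrial ribosomal proteins had a median of 0.72, which turned to -0.08 with spike-in centring (0.59, 1.32 and 0.37 by day, camera adjusted p = 3.4e-14, and adjusted p = 0.377 with an estimated correlation). Of 75, 13 rose (20 adjusted over the list alone, 47 with the block), among them MRPL19 (3.19-fold, log2 1.65, 1.70 and 1.69 by day, limma adjusted p = 0.0037; another probe log2 0.63) and MRPS35 (2.52-fold). Proteasome subunits, which degrade tagged proteins, had a median of 0.76, which turned to -0.04 with spike-in centring (0.92, 1.03 and 0.66 by day, camera adjusted p = 1.06e-11, and adjusted p = 0.0307 with an estimated correlation). Of 31 subunits, 12 rose (15 adjusted over the list alone, 20 with the block). PSMD14 rose 3.03-fold, from 3.28 ± 0.19 to 4.88 ± 0.11 (n = 4; log2 1.57, 1.67 and 1.58 by day, limma adjusted p = 0.000631; chromosome 2, 162267829 to 162267888), and PSMB3 rose 3.40-fold.

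MYC targets had a median log2 change of 0.94 in subpolysomal RNA, and 0.14 with spike-in centring (0.96, 0.95 and 0.65 by day, camera adjusted p = 5.2e-10, and adjusted p = 0.0307 with an estimated correlation). Of 27, 10 rose (18 adjusted over the list alone, 20 with the block). PA2G4, a growth-related nucleolar protein, rose 3.39-fold, from 5.23 ± 0.24 to 7.00 ± 0.33 (n = 4; limma adjusted p = 0.000205), NME1 rose 3.74-fold and GOT2 3.25-fold. MYC itself had a log2 change of 1.02 (adjusted p = 0.397, 0.0039 with the block). Heat shock proteins had a median of 0.82, and 0.02 with spike-in centring (0.79, 0.86 and 0.75 by day, camera adjusted p = 0.000281, and adjusted p = 0.0704 with an estimated correlation), and 5 of 19 rose (8 adjusted over the list alone, 9 with the block), led by FKBP4, an HSP90 cochaperone (4.65-fold), HSPD1 (3.12-fold) and HSP90AB1 (2.71-fold). Genes of the NRF2 and oxidative stress list had a median of 0.77, which turned to -0.03 with spike-in centring (0.64, 1.15 and 0.44 by day, camera adjusted p = 9.77e-05, and adjusted p = 0.377 with an estimated correlation). Of 25 measured, 4 rose (5 adjusted over the list alone, 14 with the block). SOD1, which removes superoxide, rose 3.54-fold, from 6.47 ± 0.34 to 8.29 ± 0.48 (n = 4; log2 1.501, 3.02 and 1.28 by day, limma adjusted p = 0.0015; chromosome 21, 33040890 to 33040949), and PRDX1, a peroxidase, rose 2.34-fold. Citric acid cycle genes had a median of 0.83, and 0.03 with spike-in centring (0.67, 0.95 and 0.42 by day, camera adjusted p = 0.000131, and adjusted p = 0.067 with an estimated correlation). Of 21, 3 were higher (8 adjusted over the list alone, 11 with the block), among them the malate dehydrogenases MDH1 (2.47-fold) and MDH2 (2.92-fold). NF-kB and T-cell activation genes had a median of -0.75 (-0.84, -1.05 and -0.40 by day, camera adjusted p = 0.000503, and adjusted p = 0.524 with an estimated correlation). FOS, an immediate early gene, was the 1 of 22 that fell (log2 -2.38, well above background on 3 of 4 FK866 arrays), again 1 adjusted over the list alone, and 10 fell with the block. With quantile normalization the 7 positive medians named for subpolysomal RNA ran from 0.42 to 0.60. Each list was set, after the results were seen, against 10000 random lists of like signal. The proteasome lay at percentile 99.93, the other positive lists at 100 and NF-kB genes at 0. The random lists had medians of 0.33 for oxidative phosphorylation, 0.28 for mitochondrial ribosomal, 0.33 for proteasome and 0.29 for MYC target genes. For heat shock, NRF2 and citric acid cycle genes they were 0.14, 0.19 and 0.10. Part of each positive median therefore went with signal level.

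Among single genes in subpolysomal RNA, a probe of FLCN, a tumour suppressor, rose 8.45-fold, from -0.50 ± 0.55 to 2.58 ± 1.03 (n = 4; limma adjusted p = 0.0013), while another FLCN probe gave a log2 change of 0.06. Probes of RBM33 (7.59-fold), ARMH3 (6.27-fold) and MINPP1 (6.02-fold) rose, whereas the lowest other probes of these genes gave log2 changes of -0.77, -0.52 and -0.10. RGS1 rose 5.46-fold (limma adjusted p = 0.000696; log2 2.15, 2.92 and 2.57 by day). EFEMP2, an extracellular matrix protein, fell 4.33-fold, from 2.74 ± 0.45 to 0.63 ± 0.67 (n = 4; limma adjusted p = 0.0029; log2 -2.58, -2.02 and -1.28 by day). LATS1, outside the rule here and named after its value was seen, rose by 2.18 on the log2 scale (limma adjusted p = 4.88e-05). PPFIA4 fell 4.02-fold. MTHFD2 rose 3.61-fold, from 3.53 ± 0.34 to 5.38 ± 0.18 (n = 4; limma adjusted p = 7.69e-05), and ASNS 2.08-fold (limma adjusted p = 0.0053). The cell cycle genes CCNA2 (2.76-fold) and CDK1 (2.44-fold) and the nucleolar protein NCL (2.79-fold) rose. CHAC1, which degrades glutathione, had a log2 change of -1.55 (adjusted p = 0.0833, 3.5e-05 with the block) and MCL1, an inhibitor of apoptosis, -0.81 (0.37, 0.0089 with the block).

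By limma, 985 genes changed in subpolysomal RNA, 641 higher and 344 lower, 738 of them by at least 2-fold. Scan day as a block gave 4508 (2372 higher, 2136 lower), including all 985, each with the same sign on all 3 days. The replicate block gave 4251, day 1 alone 5950 and spike-in centring 0 (1223 at an unadjusted p under 0.05). With quantile normalization 709 of 1369 calls were lower, and of 274 called genes with several probes 74 had a probe of opposite sign. The subpolysomal count was 500 without mock replicate 1, 508 without FK866 replicate 3, 560 without mock replicate 2 and 581 without FK866 replicate 1. PRDX1 lost its call without FK866 replicate 3 (adjusted p = 0.0504), MDH1 and PSMB3 without FK866 replicate 3 or mock replicate 1 or 2 (up to 0.0823 and 0.1), and ATP5MC3 without FK866 replicate 3 or 4 or mock replicate 1 or 2 (up to 0.151). FOS kept its call only without FK866 replicate 2 or 4 or mock replicate 2, HSPD1 and NCL only without FK866 replicate 3 or mock replicate 2, and MDH2 only without FK866 replicate 4 or mock replicate 3 (otherwise up to 0.135, 0.0986, 0.154 and 0.182). Calls shared by total and polysomal RNA were 14 higher and 7 lower, and those shared by total and subpolysomal RNA 41 and 14. Total RNA takes in the fractions of both other pools, so an overlap is expected.

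**Figure D1:**
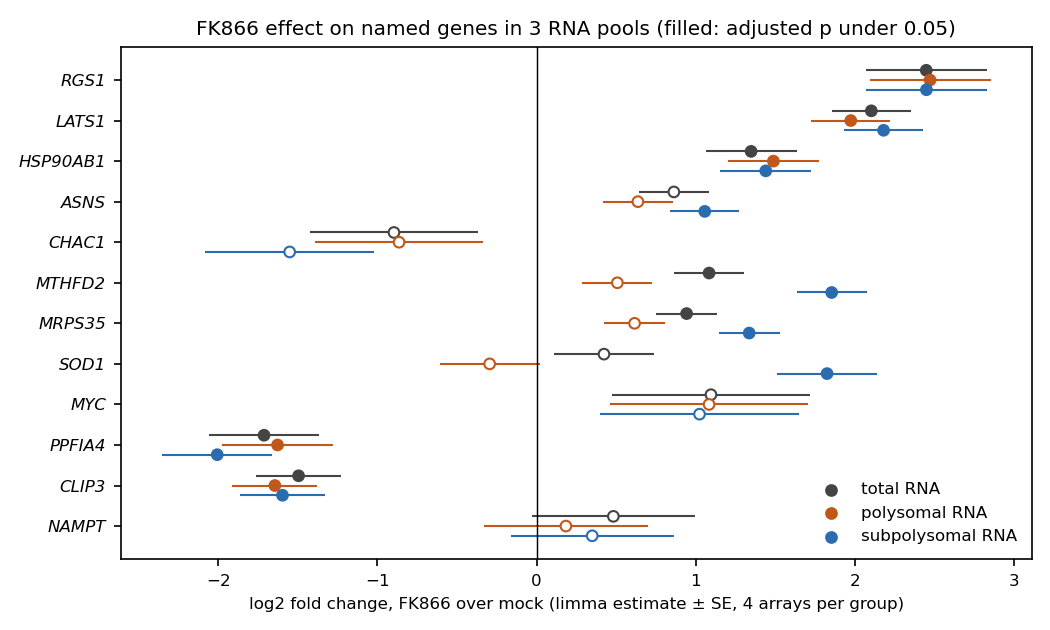
Log2 fold change with FK866 over mock (± SE, n = 4 arrays per group) of 12 genes in total, polysomal and subpolysomal RNA, with filled markers where limma's adjusted p was under 0.05. RGS1 and LATS1 rose in each pool, MTHFD2 rose by 1.08 in total and 1.85 in subpolysomal RNA, and CHAC1, MYC and NAMPT had open markers.

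The difference between the FK866 effects in polysomal and subpolysomal RNA asks which mRNAs FK866 changed differently in these pools. Oxidative phosphorylation genes had a median log2 difference of -0.93, lower in polysomal relative to subpolysomal RNA, which turned to 0.78 with spike-in centring but stayed below that of all genes under each scaling. It was -0.81, -1.28 and -1.10 by day (camera adjusted p = 4.71e-21, and adjusted p = 0.484 with an estimated correlation). Mitochondrial ribosomal proteins had a median of -0.77, which turned to 0.94 with spike-in centring (-0.58, -1.03 and -0.91 by day, camera adjusted p = 3.49e-14, and adjusted p = 0.377 with an estimated correlation), and proteasome subunits -0.58, which turned to 1.12 (-0.56, -1.05 and -0.91; camera adjusted p = 1.86e-08, and adjusted p = 0.0732 with an estimated correlation). With scan day as a block, 21 of 74 oxidative phosphorylation, 12 of 75 mitochondrial ribosomal and 7 of 31 proteasome genes fell and 0 rose. Without the block 0 of them were called over all genes, and 2, 0 and 5 fell adjusted over the list alone. MYC targets had a median of -0.65, which turned to 1.06 with spike-in centring and to 0.03 with quantile normalization or the authors' table (-0.46, -0.76 and -0.49 by day, camera adjusted p = 3.91e-06, and adjusted p = 0.122 with an estimated correlation). Of 27, 0 were called over all genes, 3 were lower adjusted over the list alone and 5 with the block. NRF2 and oxidative stress genes had -0.52, which turned to 1.19 (-0.28, -0.69 and -0.95; camera adjusted p = 0.001, and adjusted p = 0.502 with an estimated correlation). Of 25, 0 were called over all genes, 2 were lower adjusted over the list alone and 4 with the block. Cytosolic ribosomal proteins had -0.42, which turned to 1.29 with spike-in centring, 0.05 with quantile normalization and 0.07 with the authors' table (-0.28, -0.45 and -0.78 by day, camera adjusted p = 0.0117, and adjusted p = 0.944 with an estimated correlation). NF-kB and T-cell activation genes had 0.36 (0.34, 0.69 and 0.01 by day, camera adjusted p = 0.0038, and adjusted p = 0.576 with an estimated correlation). In both of these lists, of 79 and 22 genes, 0 were called by limma, 0 adjusted over the list alone and 0 with the block. Quantile normalization gave -0.48 for oxidative phosphorylation, -0.33 for mitochondrial ribosomal, -0.205 for proteasome and -0.28 for NRF2 genes. Each list was also set against 10000 random lists of like signal, a comparison chosen after the results were seen. Oxidative phosphorylation and mitochondrial ribosomal genes lay at percentile 0 (medians of their random lists -0.48 and -0.36). MYC targets lay at 3.4, NRF2 genes at 4.83, the proteasome at 10.95 and NF-kB genes at 100. Cytosolic ribosomal proteins lay at 98.92, so they fell less than random lists of like signal (median -0.545).

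Without a block, limma called 0 of 15032 genes for this difference (808 at an unadjusted p under 0.05), quantile normalization 3 and normexp 5. With scan day as a block, chosen after the data were seen, 549 passed, 43 higher and 506 lower, and 473 by at least 2-fold. A block for each culture gave 1605 and day 1 alone 1120. The genes named next were among the largest with that block. PEBP1, an inhibitor of RAF kinase, had a log2 difference of -2.21 (adjusted p = 0.0017 with the block, 0.172 without; -1.91, -2.55 and -2.48 by day; chromosome 12, 118583256 to 118583315), and SOD1 -2.12 (0.0062 with the block, 0.174 without). SMARCB1, of the SWI/SNF chromatin remodeller, had -2.30 (0.0066 with the block, 0.773 without), JPT1 -2.16 (0.0087, 0.635) and CYSTM1 -2.12 (0.0055, 0.587). Higher with the block were CLP1, an RNA kinase, at 1.40 (0.0144 with the block, 0.349 without), ARID1A, also of SWI/SNF, at 1.28 (0.0121, 0.298), and MCL1 at 1.20 (0.0363, 0.999).

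Against total RNA, limma called 0 genes for the FK866 effect on polysomal RNA (30 at an unadjusted p under 0.05, and 0 called with scan day as a block) and 0 on subpolysomal RNA (213, and 0 with the block; 64 with a block for each culture and 11 on day 1 alone). Oxidative phosphorylation genes had a median log2 difference of -0.45 in polysomal over total RNA, which turned to 0.37 with spike-in centring (-0.24, -0.89 and -0.49 by day, camera adjusted p = 1.42e-12, and adjusted p = 0.619 with an estimated correlation). In subpolysomal over total RNA they had 0.53, which turned to -0.35 with spike-in centring (0.52, 0.53 and 0.53 by day, camera adjusted p = 1.93e-15, and adjusted p = 0.546 with an estimated correlation). Mitochondrial ribosomal proteins had -0.34, which turned to 0.49 (-0.18, -0.63 and -0.44 by day, camera adjusted p = 1.58e-06, and adjusted p = 0.64 with an estimated correlation), and 0.40, which turned to -0.48 (0.34, 0.45 and 0.47; camera adjusted p = 2.25e-12, and adjusted p = 0.433 with an estimated correlation). Proteasome subunits had 0.51 in subpolysomal over total RNA, which turned to -0.37 with spike-in centring (0.53, 0.55 and 0.63 by day, camera adjusted p = 7.76e-13, and adjusted p = 0.0307 with an estimated correlation). Histones had -0.83 in polysomal over total RNA, which turned to 0.00065 with spike-in centring and was 0.13, -2.53 and -1.09 by day, so the direction did not hold on day 1 (camera adjusted p = 1.12e-10, and adjusted p = 0.624 with an estimated correlation). Adjusted over the list alone, 0 genes of these lists were called in either ratio.

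In mock cells, the ratio of polysomal to subpolysomal RNA asks which mRNAs carried many ribosomes and which few. Cytosolic ribosomal protein mRNAs were lower in polysomal RNA, with a median log2 ratio of -1.21, which was -0.32 with quantile normalization and -0.335 with the authors' table (-1.27, -0.92 and -1.33 by day, camera adjusted p = 6.98e-19, and adjusted p = 0.576 with an estimated correlation). Of 79, 30 were called lower (62 adjusted over the list alone, 79 with the block) and 0 higher. RPS3 was 4.46-fold lower, at 5.47 ± 0.51 against 7.62 ± 0.07 (n = 4; log2 ratio -2.16 ± 0.43 SE, limma adjusted p = 0.0018; -2.40, -1.44 and -2.38 by day; chromosome 11, 75111802 to 75111861). RPL37 (log2 -2.07), RPS29 (log2 -1.95) and RPS6 (log2 -1.44) were lower as well. Other TOP mRNAs, whose 5' pyrimidine tract places them under the control of mTOR, had a median of -1.30 (-1.33, -1.29 and -1.57 by day, camera adjusted p = 4.96e-13, and adjusted p = 0.0307 with an estimated correlation). Of 26, 17 were lower (20 adjusted over the list alone, 23 with the block). PABPC1, which binds poly(A) tails, was 6.86-fold lower, at 4.40 ± 0.41 against 7.17 ± 0.23 (n = 4; limma adjusted p = 6.35e-05; chromosome 8, 101715545 to 101716541), followed by EIF3E (log2 -2.24), TPT1 (log2 -2.12) and EEF1A1 (log2 -1.55). The lowest other probes of TPT1, EEF1A1 and RPS6 gave -3.56, -3.13 and -3.11. RNAs encoded by mitochondrial DNA had a median of -2.78 (-3.18, -1.80 and -3.55 by day, camera adjusted p = 9.59e-10, and adjusted p = 0.377 with an estimated correlation). Of 13, 10 were lower (12 adjusted over the list alone, 12 with the block). COX2 was 33.7-fold lower, at 2.61 ± 1.29 against 7.69 ± 0.64 (n = 4; limma adjusted p = 6.18e-05; chromosome M, 7987 to 8046), and ND4 19.2-fold.

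Noncoding hosts of snoRNAs had a median of -1.58 in mock cells (-1.70, -0.82 and -1.97 by day, camera adjusted p = 1.58e-06, and adjusted p = 0.537 with an estimated correlation). Of 13, 9 were lower (9 adjusted over the list alone, 12 with the block), with SNHG7 (log2 -2.98) and SNHG5 (log2 -2.48) in front. Another SNHG7 probe gave -0.37. The ferritin mRNAs FTL (log2 -3.03) and FTH1 (log2 -1.97) and the noncoding RNAs RPPH1 (log2 -3.43) and RMRP (log2 -3.13) were lower too. Oxidative phosphorylation mRNAs encoded in the nucleus had a median of 0.67 (0.44, 0.87 and 0.72 by day, camera adjusted p = 1.04e-05, and adjusted p = 0.852 with an estimated correlation). Of 74, 17 were higher and 1 lower (23 and 2 adjusted over the list alone, 38 and 5 with the block). NDUFC2, of complex I, was 4.29-fold higher, at 6.74 ± 0.29 against 4.64 ± 0.29 (n = 4; limma adjusted p = 0.000109), and NDUFA8 3.43-fold. Mitochondrial ribosomal proteins had a median of 0.53 (0.41, 0.58 and 0.67 by day, camera adjusted p = 0.0026, and adjusted p = 0.852 with an estimated correlation). Of 75, 12 were higher and 3 lower (14 and 4 adjusted over the list alone, 36 and 11 with the block). Proteasome subunits had 0.49 (0.56, 0.55 and 0.74 by day, camera adjusted p = 5.11e-05, and adjusted p = 0.269 with an estimated correlation). Of 31, 10 were higher and 0 lower (10 adjusted over the list alone, 16 with the block), among them PSMB2 (5.09-fold) and PSMB6 (3.96-fold). Among random lists of like signal, the proteasome median lay at percentile 91.02 (range of 95% of them -0.12 to 0.60). The other lists named for mock cells lay outside that range of their own random lists. For cytosolic ribosomal proteins the random lists had a median of -0.69, so part of their -1.21 went with signal level. No such comparison was made for the ratio in FK866 cells. No list median named for mock cells changed sign under another scaling. Single genes higher in polysomal RNA were RAD54L2 (8.01-fold), AGO1, an argonaute protein (7.90-fold; its other probe log2 0.80), and PAIP2B, an inhibitor of PABPC1 (6.06-fold). KRTAP19-2, a keratin-associated protein (log2 -6.74), and C20orf141 (log2 -5.58) were far lower in polysomal RNA.

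By limma, 2341 genes differed between the pools in mock cells, 1166 higher and 1175 lower in polysomal RNA, 1925 of them by at least 2-fold. Scan day as a block gave 6998 (3362 higher, 3636 lower), the replicate block 6803, a block for each culture 7902, and 2312 of the 2341 had the same sign on all 3 days. Median centring gave 2930 higher and 809 lower, and spike-in centring 78 calls, 76 of them lower. Of 553 called genes with several probes, 446 had all their probes on the same side of 0. The count was 1514 without mock polysomal replicate 4. RPS29 lost its call without mock polysomal replicate 1 or 2 or mock subpolysomal replicate 3 or 4 (adjusted p up to 0.0644).

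In FK866 cells, the same ratio placed ribosomal protein mRNAs low in polysomal RNA again. Cytosolic ribosomal proteins had a median log2 ratio of -1.65, which turned to 0.08 with spike-in centring and was -0.29 with quantile normalization and -0.28 with the authors' table (-1.55, -1.37 and -2.13 by day, camera adjusted p = 3.87e-27, and adjusted p = 0.509 with an estimated correlation). Of 79, 67 were called lower (79 adjusted over the list alone, 79 with the block). RPS6 was 3.58-fold lower, at 7.64 ± 0.50 against 9.48 ± 0.57 (n = 4; log2 ratio -1.84 ± 0.34 SE, limma adjusted p = 0.0011; -1.64, -1.64 and -2.44 by day). Also lower were RPS12 (log2 -2.67), RPL39 (log2 -2.44), RPS29 (log2 -2.24) and RPL37 (log2 -2.23). Other TOP mRNAs had a median of -1.46, which turned to 0.28 with spike-in centring (-1.54, -1.11 and -1.83 by day, camera adjusted p = 2.86e-13, and adjusted p = 0.0307 with an estimated correlation). Of 26, 18 were lower (22 adjusted over the list alone, 24 with the block). PABPC1 was 4.95-fold lower (limma adjusted p = 0.000377), TPT1 4.36-fold, and EEF1A1 had a log2 ratio of -1.49 that turned to 0.25 with spike-in centring. RNAs encoded by mitochondrial DNA had a median of -2.86 (-3.04, -1.72 and -3.55 by day, camera adjusted p = 8.94e-09, and adjusted p = 0.391 with an estimated correlation). Of 13, 11 were lower (12 adjusted over the list alone, 13 with the block), COX2 by 17.9-fold and ND4 by 16.7-fold. Noncoding hosts of snoRNAs had a median of -1.82 (-2.01, -1.01 and -2.52 by day, camera adjusted p = 5.51e-08, and adjusted p = 0.481 with an estimated correlation). Of 13, 10 were lower (10 adjusted over the list alone, 13 with the block). Neither of these last medians changed sign with spike-in centring (-1.12 and -0.08).

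In contrast to mock cells, oxidative phosphorylation genes had a median of -0.32 in FK866 cells, which turned to 1.42 with spike-in centring, 0.18 with quantile normalization or the authors' table and 0.10 with median centring (-0.30, -0.51 and -0.37 by day, camera adjusted p = 0.0983). Of 74, 6 were lower and 1 higher (6 and 1 adjusted over the list alone, 23 and 1 with the block), among them UQCRB (log2 -1.32) and UQCRC2 (log2 -1.21) of complex III. Mitochondrial ribosomal proteins had a median of -0.30, which turned to 1.44 with spike-in and 0.11 with median centring (-0.35, -0.33 and -0.30 by day, camera adjusted p = 0.103), with 8 of 75 lower and 1 higher (8 and 1 adjusted over the list alone, 29 and 5 with the block), among them MRPL45 (log2 -1.32) and MRPS33 (log2 -1.26). With spike-in centring UQCRB, UQCRC2, MRPL45 and MRPS33 turned to 0.42, 0.53, 0.41 and 0.47. Proteasome subunits had a median of -0.0082, which was positive under every other scaling, from 0.12 with normexp to 1.73 with spike-in centring (0.00, -0.40 and 0.07 by day, camera adjusted p = 0.795 in the upward direction, opposite in sign to the median), with 1 higher and 2 lower of 31 (0 and 0 adjusted over the list alone, 5 and 8 with the block). ARID1A was 6.06-fold higher in polysomal RNA (limma adjusted p = 2.37e-06), AGO1 6.51-fold (its other probe log2 0.22) and RAD54L2 5.86-fold.

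By limma, 1989 genes differed between the pools in FK866 cells, 793 higher and 1196 lower in polysomal RNA, 1633 of them by at least 2-fold. Scan day as a block gave 6878 (2478 higher, 4400 lower), the replicate block 6685, a block for each culture 7778, and 1955 of the 1989 had the same sign on all 3 days. Spike-in centring gave 2116 higher and 18 lower, and of 526 called genes with several probes 125 had a probe of opposite sign. The count was 1237 without FK866 polysomal replicate 2 and 3108 without FK866 polysomal replicate 3. RPS12 kept its call only without replicate 3 of polysomal RNA or replicate 2 of subpolysomal RNA (otherwise adjusted p up to 0.194). Of genes called in mock and FK866 cells alike, 450 were higher in both and 773 lower in both, where independent lists give 61.5 and 93.5, and 1 went opposite ways.

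**Figure D2:**
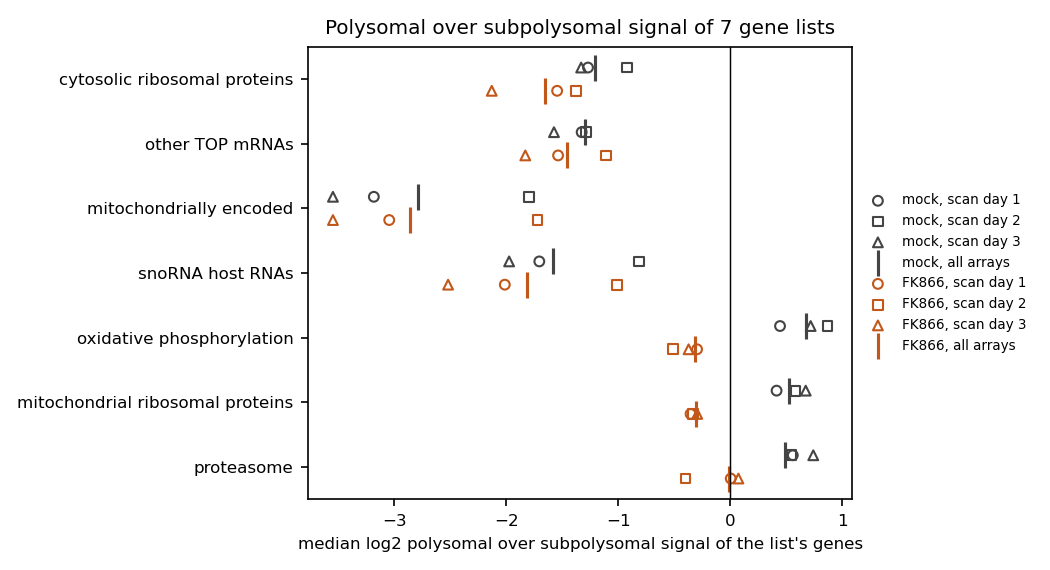
Median log2 ratio of polysomal to subpolysomal RNA of 7 gene lists in mock and FK866 cells (bars, all 4 replicates; markers, each scan day). The bar of oxidative phosphorylation genes is at 0.67 in mock and -0.32 in FK866 cells, and with spike-in centring the FK866 bars of the cytosolic ribosomal (0.08), other TOP (0.28), oxidative phosphorylation (1.42), mitochondrial ribosomal (1.44) and proteasome (1.73) lists turn positive; median centring turns the last 3 of these and quantile normalization the oxidative phosphorylation and proteasome bars, as do the authors' values, and normexp the proteasome bar.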

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

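The check for outlying arrays and the list tests were planned; the scan-day block, the other splits of the arrays, the comparison of probes within a gene and the tests of explanations were chosen after the results were seen. In 25 of 272 groups of 4 arrays tested, for the named genes and for each array's 75th percentile and share of probes above background, 1 array lay far from the other 3 (its gap to the nearest, over the range of all 4, was above Dixon's critical value). Chance gives about 1 in 20 for independent groups of like arrays. Here replicates 1 and 2 share scan day 1 and the groups reuse the same arrays, so 25 of 272 cannot be set against that rate. The outlying array was replicate 3, of scan day 2, in 20 of the 25 and replicate 4, of scan day 3, in the other 5, and none was of scan day 1. The values in FK866 subpolysomal RNA were 0.918 for SOD1, 0.886 for PEBP1, 0.872 for PSMB3, 0.851 for MINPP1, 0.846 for ARMH3, 0.839 for SMARCB1 and 0.837 for CYSTM1. In FK866 polysomal RNA they were 0.908 for DDIT3, 0.894 for UQCRB, 0.857 for ND4, 0.856 for RPS6, 0.840 for PEBP1 and 0.838 for EEF1A1, and in FK866 total RNA 0.876 for FBLN5. Mock polysomal RNA gave 0.901 for NDUFC2, 0.844 for PAIP2B, 0.839 for ND4 and 0.831 for C20orf141. Mock subpolysomal RNA gave 0.913 for RAD54L2, 0.878 for CHAC1, 0.871 for COX2, 0.860 for SDHD, 0.834 for ND4 and 0.8292 for FOS, and mock total RNA 0.867 for MRPS35.

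By camera at its preset correlation, the effect of FK866 differed between RNA pools for several lists, of which the proteasome in subpolysomal over total RNA alone passed with an estimated correlation (adjusted p = 0.0307, the others 0.0732 to 0.944). Spike-in centring turned the sign of each median given here except that of NF-kB and T-cell activation. In polysomal over total RNA the median log2 difference was -0.45 for oxidative phosphorylation, -0.34 for mitochondrial ribosomal proteins and -0.83 for histones. In subpolysomal over total RNA it was 0.53 for oxidative phosphorylation, 0.40 for mitochondrial ribosomal proteins and 0.51 for the proteasome. In polysomal over subpolysomal RNA it was -0.93 for oxidative phosphorylation, -0.77 for mitochondrial ribosomal proteins, -0.58 for the proteasome, -0.65 for MYC targets (0.03 with quantile normalization or the authors' table), -0.52 for NRF2 and oxidative stress genes, -0.42 for cytosolic ribosomal proteins (0.05 with quantile normalization, 0.07 with the authors' table) and 0.36 for NF-kB and T-cell activation. For single genes, 549 passed this test with scan day as a block.

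The first pattern is a lower FK866 effect in polysomal than in subpolysomal RNA on genes of oxidative phosphorylation, the mitochondrial ribosome and the proteasome. In polysomal RNA, camera at its preset correlation called 2 lists lower with FK866, hypoxia genes and histones, and none of these 3. The pattern therefore does not show that their mRNAs left the polysomes. For this difference between effects, the lists' medians stayed below that of all genes within each scan day (highest difference -0.56). The same held without the dim FK866 replicate 3 arrays (-0.36). This argues against scan day and those arrays as the cause. Of the scalings, only quantile normalization, the authors' table and normexp can move a list against all genes. As means over cultures, quantile normalization cut the differences from -0.875 ± 0.09 SE to -0.40 ± 0.08 for oxidative phosphorylation, from -0.72 ± 0.07 to -0.39 ± 0.07 for mitochondrial ribosomal genes and from -0.58 ± 0.14 to -0.10 ± 0.17 for the proteasome. Scaling as the whole cause is argued against for the first pair of lists (highest -0.38 under the 3 scalings) and stays open for the proteasome. Signal level as the whole cause is argued against for oxidative phosphorylation and mitochondrial ribosomal genes (percentile 0 among 10000 random lists of like signal). Those random lists had medians of -0.48 and -0.36, against -0.93 and -0.77 for the lists, so part of each shift went with signal level. For the proteasome signal level stays open (percentile 10.95). A candidate explanation, offered as a hypothesis found and tested on the same data, is that FK866 lowered ribosome loading of mRNAs for oxidative phosphorylation and mitochondrial ribosomes relative to other mRNAs. Spike-in centring turned the sign of the medians themselves, though its offset varied between arrays of a group by an SD of 1.01 to 1.73 log2 and the labels do not say whether equal cRNA was hybridised from each pool. With an estimated correlation none of the 3 lists passed (adjusted p = 0.484, 0.377 and 0.0732).

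The second pattern, in pairs of probes of which the gene comparisons use at most 1, is that probes lying upstream in a gene rose over downstream probes of the same gene: of 3412 pairs, the upstream probe rose over the downstream one by more than 1 log2 in 260 in total RNA and the reverse held in 36. In 82 of the 260 the upstream probe was the one used for the gene. Of pairs over 10000 bases apart, 157 and 17 went these ways in total RNA and 253 and 40 in subpolysomal RNA, and with normexp 62 and 3, and 128 and 10. In total and subpolysomal RNA, near pairs argue against a general shift from RNA integrity or labelling from the 3' end within 2000 bases. The highest median of near pairs was -0.0091 there, though genomic distance stands in for transcript distance. Among near pairs, the upstream probe rose over the downstream one by more than 1 log2 in 19 in total RNA, and the reverse held in 13. In subpolysomal RNA these were 45 and 18. For such large differences an effect of this kind stays open in both pools. The general shift stays open in polysomal RNA (median 0.0913). Near pairs cannot speak to such an effect over longer distances, which stays open in each pool. Signal level is argued against (median 0.30 where the upstream probe was the brighter). More nuclear RNA in the lysate cannot be told apart, since the nuclear RNA list had a median of 0.17 with members going both ways. Chance differences between arrays stay open in each pool. In total and subpolysomal RNA the exact two-sided permutation p of far pairs was 0.1429 and 0.0571 over all arrays, which allow 0.0286. Within scan days it was 0.0833 in both, the smallest possible there, and the difference was positive for 4 of 4 same-numbered arrays in each. In polysomal RNA these permutation p were 0.2 and 0.1667, with 3 of 4 positive. By day the mean far-pair difference was 0.31, 0.55 and 0.13 in total, 0.25, 0.86 and -0.05 in polysomal and 0.45, 0.44 and 0.19 in subpolysomal RNA. The hypothesis that FK866 raised transcripts ending upstream was set against the largest changes in these same pairs. In pairs over 10000 bases apart, 114 upstream probes rose by over 1 log2 and 31 downstream probes fell as far, 3.68 to 1. The hypothesis allows this ratio. It cannot be told by the ratio from more nuclear RNA or from an integrity effect over longer distances. Examples in total RNA, named after their values were seen, are RBM33 (2.00 upstream, -0.24 downstream), ARMH3 (1.89, -0.19) and RNF213 (1.83, -0.44).

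Each comparison was repeated over the 35 splits of its 8 arrays, or 8 cultures for the differences between effects, the real split included. Without a block, no other split had as many calls as the real one in total RNA (1 split as large, 59 real, 0 in the highest other) or within mock cells (1, 2341, 0). These 35 splits also exchange arrays between scan days, and the splits that keep to scan days are too few. Chance is therefore not excluded in either comparison. In polysomal RNA it is not excluded (2 splits; 36 real, 4167 in the highest other, which parts scan day 1 from the later days), and in subpolysomal RNA the same scan-day split gave 1391 against 985 real (2 splits as large). Within FK866 cells it is not excluded either (3; 1989, 2403, the latter with FK866 polysomal replicates 1, 2 and 4 and subpolysomal replicate 1 on one side). The effects on polysomal and on subpolysomal RNA against total RNA had 0 calls in the real split, so all 35 splits were as large (highest other 0 for both), and for polysomal over subpolysomal RNA the real count of 0 was matched by all 35 (highest other 2). In fits with scan day as a block, labels can be exchanged within days only, and those 12 splits are too few for a share under 0.05. The real and the highest other counts were then 1269 and 0 in total, 1276 and 620 in polysomal and 4508 and 1 in subpolysomal RNA, 549 and 0 for polysomal over subpolysomal RNA, 6998 and 139 within mock cells and 6878 and 1822 within FK866 cells. The split of the polysomal arrays by scan day, with many times the real count, points to a structure of the arrays. The 8 splits that part all same-numbered arrays, also too few for a share under 0.05, gave at most 0 other than the real one without a block, and up to 620, 139 and 1822 with it in polysomal RNA, mock cells and FK866 cells.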

How the results depend on the processing

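Scan day as a block, scan day 1 alone, leaving out both dim arrays and leaving out scan day 3 were chosen after the data were seen; the rest were planned. Of 2676 values of called named genes over all settings, 2209 kept direction and side of the threshold, 462 kept the direction and no longer passed, and 5 changed sign; of 308 values of called lists the counts were 245, 62 and 1. Of 636 values of uncalled genes 553 stayed, 82 passed and 1 changed sign, and of 21 values of uncalled lists 15, 2 and 4. All 103 called genes kept their calls with the replicate block, scan day as a block and day 1 alone, 50 with only the groups compared in the fit and 8 with spike-in centring. Of the list calls, 44 were followed over the settings, and all 44 held with the replicate and scan day blocks. The list calls lost with the scan day block, named under the processing, are not among them. The share of probes well above background, 43.1% to 67.8%, limits which genes could be tested.

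Counts are given in the order total, polysomal and subpolysomal FK866 effects, effect on polysomal over subpolysomal RNA, and that ratio in mock and in FK866 cells, where they differ by over 1.5 times from 59, 36, 985, 0, 2341 and 1989. The replicate block gave 1078, 1123, 4251, 389, 6803 and 6685; same-numbered arrays share a scan day, and for polysomal RNA their correlations were 0.77, 0.76, 0.78 and 0.0032 (1 of 4 arrays matched its own number best). The replicate block per treatment, or culture, was fitted in 2 ways whose counts cannot be compared with each other. As a random effect (limma's duplicateCorrelation) it gave 7, 2 and 375 for the FK866 effects. As a fixed block it gave 1605, 7902 and 7778 for the others, and 64 for subpolysomal over total RNA. Scan day as a block gave 1269, 1276, 4508, 549, 6998 and 6878, and day 1 alone 2488, 1957, 5950, 1120, 7728 and 7172, and 11 for subpolysomal over total RNA. Slide as a block gave 223, 237, 1791, 5044 and 4672 for the comparisons other than the difference. With only the groups compared in the fit, which leaves fewer arrays for the error, limma gave 0 in total RNA (920 at an unadjusted p under 0.05), 0 in polysomal RNA (597), 101 in subpolysomal RNA and 229 in FK866 cells. No filter gave 16, 4, 389, 1502 and 1229 outside the difference; the mean over probes gave 28 in total RNA. Leaving out both dim arrays gave 126 in total and 56 in polysomal RNA, and leaving out scan day 3 gave 17 in polysomal RNA, 896 in mock and 716 in FK866 cells. List calls went from 87 to 8 with an estimated correlation and 35 with fry.

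Among scalings, median centring gave 32 in total RNA (8 higher, 24 lower, against 45 and 14), 3 in polysomal RNA (1 and 2, against 24 and 12), 3739 in mock cells (2930 and 809, against 1166 and 1175) and 1745 higher and 908 lower in FK866 cells (against 793 and 1196). Spike-in centring gave 0 in total, 0 in polysomal and 0 in subpolysomal RNA, 78 in mock cells (2 higher, 76 lower), and 2116 higher and 18 lower in FK866 cells. Quantile normalization and the authors' table each gave 3 for polysomal over subpolysomal RNA and shifted the split to 54 higher and 30 lower (53 and 30 with the authors' values) in total RNA, 660 and 709 (656 and 712) in subpolysomal RNA, and 1387 and 1213 (1395 and 1206) in FK866 cells. Normexp gave 22 in total RNA (21 and 1), 5 for the difference, and splits of 25 and 7 in polysomal, 523 and 150 in subpolysomal RNA and 806 and 2045 in FK866 cells. Sign changes under spike-in centring were CHAC1 in polysomal RNA (0.041) and, in FK866 cells, EEF1A1 (0.25), UQCRB (0.42), UQCRC2 (0.53), MRPL45 (0.41) and MRPS33 (0.47). Test directions turned for cytosolic ribosomal proteins in the difference with quantile normalization (0.0498) and, in FK866 cells, for oxidative phosphorylation with quantile normalization (0.18) and normexp (-0.14), mitochondrial ribosomal proteins with normexp (-0.21) and the proteasome with fry (-0.0082). The cause of these differences was not tested.

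With 1 array left out, counts ranged from 13 to 71 in total RNA, 5 to 43 in polysomal RNA, 500 to 1064 in subpolysomal RNA, 1514 to 2082 in mock cells and 1237 to 3108 in FK866 cells, and were 0 for the 3 differences. Values of called genes kept the call in 682 cases and lost it in 142.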

Other observations

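The list tests given here were planned, and the medians by scan day were chosen after the data were seen. Targets of ATF4, the transcription factor of the integrated stress response, had a median log2 change of 0.12 in total RNA (31 measured, camera adjusted p = 0.493). In subpolysomal RNA it was 0.17 (adjusted p = 0.385), and -0.04 with quantile normalization and -0.63 with spike-in centring. Their member MTHFD2 rose in total RNA, and MTHFD2 and ASNS rose in subpolysomal RNA. Messenger RNAs with upstream reading frames had a median of 0.14 in total RNA (16 measured, adjusted p = 0.548). The further lists called in subpolysomal RNA had positive medians there that spike-in centring made negative, from -0.29 for translation initiation factors to -0.66 for proliferation genes. Spliceosome genes had a median of 0.43 (0.47, 0.78 and 0.19 by day, camera adjusted p = 0.000579, and adjusted p = 0.546 with an estimated correlation; -0.37 with spike-in centring). Of 38, 8 rose (11 adjusted over the list alone, 17 with scan day as a block), among them the core component SNRPD3 (3.23-fold). Translation initiation factors had 0.51 (0.55, 0.73 and 0.34 by day, camera adjusted p = 0.000153, and adjusted p = 0.0665 with an estimated correlation), and 4 of 32 rose (10 adjusted over the list alone, 15 with the block). Unfolded protein response genes had 0.46 (0.33, 0.61 and 0.04 by day, camera adjusted p = 0.0131, and adjusted p = 0.349 with an estimated correlation; -0.34 with spike-in centring). Of 26, 5 rose (6 adjusted over the list alone, 10 with the block), among them the chaperone DNAJC3 (3.11-fold). Autophagy and lysosome genes had 0.17 (0.23, 0.56 and -0.0019 by day, camera adjusted p = 0.0285, and adjusted p = 0.785 with an estimated correlation; -0.63 with spike-in centring). Of 39, 4 rose and 1 fell (5 and 2 adjusted over the list alone, 14 and 4 with the block). Among them ATG3, which lipidates LC3, rose 3.02-fold, and a probe of the lysosomal membrane protein LAMP2 rose 3.34-fold while another gave a log2 change of -0.19. Proliferation genes had 0.14 (0.10, 0.26 and 0.24 by day, camera adjusted p = 0.0256, and adjusted p = 0.589 with an estimated correlation), and 4 of 30 rose (5 adjusted over the list alone, 9 with the block). Cholesterol synthesis genes had 0.11 (adjusted p = 0.439; -0.69 with spike-in centring and -0.04 with quantile normalization or the authors' table). Of 23, 2 rose, such as ACAT2 (2.32-fold), and 2 fell, such as LSS, whose call ended without FK866 replicate 3 or mock replicate 1 or 3 (adjusted p up to 0.0799).

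The remaining medians are for total RNA, and no called list among them changed sign under another scaling. Oxidative phosphorylation had 0.31 (camera adjusted p = 2.96e-06, and adjusted p = 0.836 with an estimated correlation) and the proteasome 0.35 (0.000104, and adjusted p = 0.306 with an estimated correlation). Translation initiation factors had 0.39 (0.000189, and adjusted p = 0.0665 with an estimated correlation) and spliceosome genes 0.28 (0.000204, and adjusted p = 0.524 with an estimated correlation). The citric acid cycle had 0.39 (0.0036, and adjusted p = 0.203 with an estimated correlation) and NRF2 genes 0.28 (0.0285, and adjusted p = 0.665 with an estimated correlation). Proliferation genes had 0.23 (0.01, and adjusted p = 0.546 with an estimated correlation). On scan day 3 the medians of these lists were -0.25, -0.19, -0.10, -0.12, -0.0049 and -0.22, and 0.55 for proliferation, so the direction held on that day for proliferation only.

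Camera did not call these other lists in total RNA. Histones had a median of 0.26 (adjusted p = 0.0743), cytosolic ribosomal proteins 0.05 (0.73), other TOP mRNAs 0.13 (0.201), DNA replication genes 0.16 (0.229) and unfolded protein response genes 0.17 (0.155). Autophagy genes had 0.06 (0.439), p53 targets -0.21 (0.409), interferon genes -0.01 (0.961), NAD metabolism -0.03 (0.715) and glycolysis 0.01 (0.657). Cholesterol synthesis had -0.13 (0.495), fatty acid synthesis -0.09 (0.73), energy stress genes -0.13 (0.887) and apoptosis genes 0.13 with a mean of -0.03 (0.84). KRAB zinc finger genes had -0.11 (0.955), nuclear RNAs 0.17 (0.618), mitochondrial RNAs -0.17 (0.563) and snoRNA hosts 0.20 (0.36). Among markers of other cells, 7 of 12 erythroid genes were measured (median 0.19, adjusted p = 0.847), 8 of 16 myeloid (0.06, 0.874), 5 of 12 B-cell (0.12, 0.928) and 2 of 12 epithelial or fibroblast genes (-0.08, 0.813). T-cell identity genes, 35 of 36 measured, had -0.02 (0.778).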
